A study of Bemisia tabaci with 18 samples.

How the data were processed

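Total RNA of TH-R and TH-S whiteflies was hybridised to a 1-colour Agilent array of 60-base probes, after Cy3 labelling of cRNA prepared from 2 µg of RNA with a linear amplification kit, per the labels' protocols. The 18 arrays fall into 6 groups of 3, for 2 strains and 3 stages, taken from the strain and stage given in the labels. Each array file holds 15208 non-control spots for 8394 probe IDs with 7211 distinct sequences. A probe has 1 spot (4936 IDs) up to 10 spots (237 IDs), and 634 sequences carry more than 1 ID.

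The processed signal in the deposited scanner files is an intensity made by Agilent Feature Extraction 10.7.1.1, per the file headers. It was background-subtracted, corrected by spatial and multiplicative detrending within each array, and set to a surrogate value for spots not above background, per the file headers. No normalization between arrays was applied to it. The mean spot signal and median local background, also intensity values per the file headers, entered 1 alternative. The deposited value table lists 6226 of the 8394 probes in log2 units, with column medians from 7.02 to 7.43 and a minimum near 1.55. Each column correlated with the log2 processed signal of its own array at 0.9896 to 0.9959. The submitters' processing notes name limma 3.15.4 and R 2.15.1 without further detail, so the background correction and the way its values were scaled between arrays stay unknown. Its scale is log2 and its direction is that of the signal. It was used as an alternative.

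The log2 processed signal of each array minus the array's 75th percentile over non-control spots was analysed. Spots with an outlier mark were left out and the other spots of a probe were averaged. A probe was measured on an array when at least 50% of its remaining spots were marked well above background by the scanner software. Probes measured on all 3 arrays of at least 1 group were tested, 5623 IDs with 4866 distinct sequences. Of these, 3602 were measured on all 18 arrays. One linear model with a mean per group was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, which leaves 12 residual degrees of freedom. Contrasts compared TH-R with TH-S in each stage, nymph with egg and adult female with nymph (means over both strains), and an F test covered the 2 strain-by-stage interaction terms. Tests were two-sided, and a Benjamini-Hochberg adjusted p under 0.05 over all tested probes was called. Design, filters, alternatives and the rule for named probes were fixed before the data were examined.

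A probe measured on all 3 arrays of one group and on none of the other has only a bound there. Its fold is the mean of the bright group against the mean, per array, of the higher of the lowest signal among measured probes and the dim probe's own signal, given as "at least". Calls of one direction in all 3 stages were set beside the number that independent lists would share. The list that pairs probe IDs with genes is not among the tables used here: every description column reads unknown and 0 of 8394 IDs are in the reference gene table. The gene lists fixed beforehand, such as P450s and glutathione S-transferases, were therefore not tested. The rule named, per contrast, the 2 largest rises and 2 largest falls among called probes measured on all arrays compared and with no overlap between the groups. It named the 4 smallest p-values for the interaction, and for calls shared by the stages the 2 each way with the largest smallest change.

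The array files give slide and scan day. Slides 1 and 2 and scan day 1 hold the TH-R arrays, with TH-R adult replicate 3 alone on slide 2. Slides 3 and 4 and scan day 2 hold the TH-S arrays, with TH-S egg replicate 1 alone on slide 3. Slide entered stage and interaction contrasts as a fixed block and strain contrasts as a random block. As slides 2 and 3 hold 1 array each, the fixed block only sets those arrays aside. It makes no adjustment of slide 1 against slide 4. The variance between arrays of a group was 2.8 to 10.1 times that of the mean of repeated spots, so the arrays of a group are not rescans of 1 hybridisation.

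The script was tested on simulated data with the means and the spread of the 5623 probes, 200 of them changed by 4 sizes of fold. With 1 spread shared by the groups, 150 of the 200 changed probes were called in each strain comparison, and 11 of 5423 unchanged probes were called in eggs, 4 in nymphs and 3 in adults. At 2-fold, 47, 43 and 41 of 50 were called. With each group's own spread, 206 unchanged probes were called in eggs, 33 in nymphs and 42 in adults, and a weight per group gave 63, 61 and 59. With each group's own spread the simulated calls, most of all in eggs, therefore held more false ones than the adjusted p states. Only 200 probes were changed there, far fewer than were called in the data. A group's own spread was taken from 3 arrays, which overstates how far the groups differ in spread. Probes were also drawn independently, without shifts common to an array. The share of false calls therefore does not carry over. For nymph against egg 178 of 200 probes changed by 2-fold and 13 unchanged ones were called with the shared spread, and 188 and 73 with each group's own. For the interaction these counts were 158 and 5, and 158 and 85.

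Alternatives were quantile normalization, median scaling, normexp with an offset of 50 and quantile normalization, the deposited value table, no filter on dim probes, only probes measured on all 18 arrays, the replicate number as a block, slide as a block, the arrays of the compared stages alone, eBayes with trend and robust, array weights, a 2-fold threshold, and each array left out in turn. A weight per group, a filter for probes measured on all 6 arrays of a stage and stage contrasts within slide 1 and slide 4 were added after the data were seen. Probe sequences were translated with Biopython 1.88 in Python 3.11.15 to search for protein signatures, and figures were drawn with matplotlib 3.10.9.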

Results

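Transcript levels were measured in whole whiteflies, Bemisia tabaci of the B biotype, from a strain resistant to the insecticide thiamethoxam (TH-R) and a susceptible strain (TH-S), both reared on cabbage. Per the labels, TH-R had lived under the insecticide for over 60 generations and its resistance was above 70-fold that of TH-S. Each strain was sampled as eggs collected within 24 h, as nymphs of the fourth instar and as unmated adult females aged 1 day. Each of the 6 groups had 3 arrays, 18 in all, and each array was hybridised with Cy3-labelled RNA of 1 sample. The number of arrays limits the precision. The labels do not say whether the 3 arrays of a group came from separate cultures.

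The 75th percentile of the signal lay between 155.5 and 638 intensity units, lowest on TH-R egg replicate 3. Spots well above background made up 53.95% to 78.05% of the spots of an array, and no spot was saturated. Correlations across probes between arrays of a group were 0.9882 to 0.9986. The median SD of a probe within a group was 0.147 on the log2 scale in TH-R eggs and 0.0488 to 0.0633 in the other 5 groups. Probes well above background on all 3 arrays numbered 4266 in TH-R eggs, 4417 in TH-S eggs, 4704 in TH-R nymphs, 4986 in TH-S nymphs, 4894 in TH-R adult females and 4643 in TH-S adult females. The files do not pair probe IDs with gene names, so probes are given by ID. Levels of single probes are log2 signal relative to the 75th percentile of the array, as mean ± SD with n = 3, and adjusted p-values are from limma.

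The first component of variance, 71.9%, separated eggs from nymphs and adults. The second, 16.8%, separated nymphs from adult females, and the third, 4.03%, separated the strains in all 3 stages. The TH-R arrays were on slides 1 and 2 and were scanned on day 1, and the TH-S arrays were on slides 3 and 4 and were scanned on day 2. Strain is therefore confounded with slide and scan day in each strain comparison below.

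**Figure D1:**
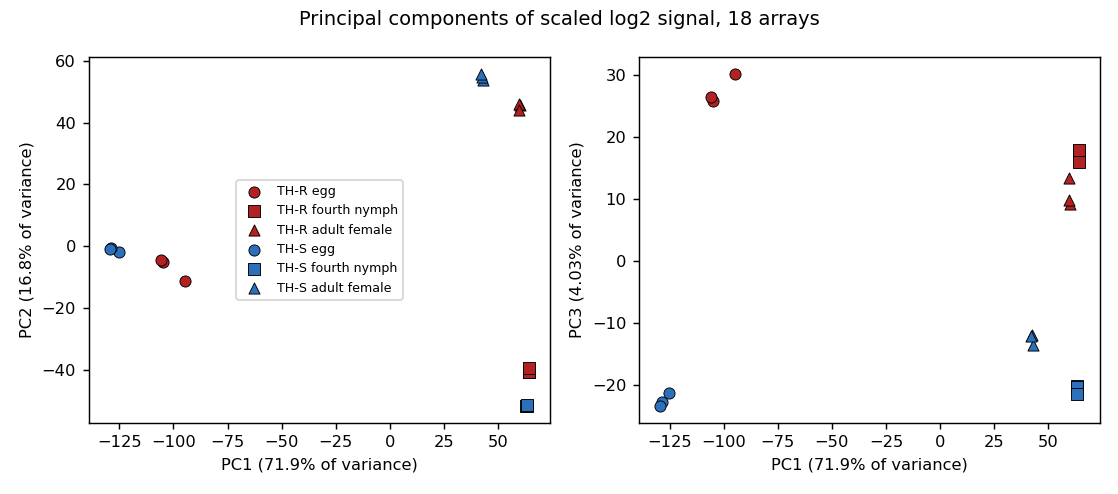
Scores of the 18 arrays on the first 3 principal components of log2 signal scaled to the array's 75th percentile, in arbitrary units, with colour for strain and symbol for stage. The first 2 components (71.9% and 16.8% of the variance) separate the stages and the third (4.03%) separates TH-R from TH-S.

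The comparison of the strains in eggs addressed which transcripts differ before feeding starts. The largest rises in TH-R eggs among probes measured on all 6 egg arrays were those of p_05809 and p_00429. Probe p_05809 was at 2.55 ± 0.22 in TH-R and -3.66 ± 0.06 in TH-S eggs, 74.1-fold higher in TH-R. Probe p_00429 was at 3.48 ± 0.15 and -2.59 ± 0.28, 67.3-fold higher in TH-R. The largest falls were those of p_00822, at -1.67 ± 0.05 in TH-R and 1.01 ± 0.04 in TH-S eggs (6.4-fold), and of p_06620, at -4.17 ± 0.51 and -1.84 ± 0.03 (5.01-fold). The log2 differences were 6.21 with a standard error of 0.08 for p_05809 (adjusted p = 4.77e-16), 6.07 ± 0.13 for p_00429 (8.5e-14), -2.68 ± 0.04 for p_00822 (3.96e-15) and -2.32 ± 0.16 for p_06620 (1.71e-08).

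Of 5623 probes tested with limma, 2328 were higher and 1530 lower in TH-R eggs, 3858 in all. These calls include 266 of the 557 tested probes measured on no egg array, 131 of them at least 2-fold higher in TH-R. A change of at least 2-fold was seen for 825 higher and 121 lower probes, against 342 and 278 with quantile normalization, 291 and 1116 with median scaling, 109 and 36 with normexp and 256 and 200 in the deposited values. Among the 4113 probes well above background on all 6 egg arrays, 386 were at least 2-fold higher and 75 at least 2-fold lower, against 181 and 71 with quantile normalization, 129 and 948 with median scaling, 99 and 26 with normexp and 140 and 47 in the deposited values. A further 33 probes were well above background in TH-R eggs and on no TH-S egg array, up to at least 86.9-fold higher, and 23 probes had the opposite pattern, up to at least 62.7-fold lower in TH-R. The balance of the egg calls depended on the scaling. Of the called probes 60.3% were higher in TH-R with the 75th percentile, against 45% with quantile normalization, 19% with median scaling, 44.4% with normexp and 42.7% in the deposited value table. The median log2 difference over all tested probes was 0.174 with the 75th percentile and -0.477 with median scaling, and TH-R eggs were the group with the widest spread and the dimmest array.

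In nymphs, the last stage before adult emergence, the largest rises in TH-R among probes measured on all 6 nymph arrays were those of p_07502 and p_00562. Probe p_07502 was at 2.63 ± 0.01 in TH-R and -0.97 ± 0.01 in TH-S nymphs, 12.1-fold higher in TH-R. Probe p_00562 was at 1.96 ± 0.03 and -1.61 ± 0.02, 11.8-fold higher. The largest falls were those of p_07551, at -4.02 ± 0.09 in TH-R and -0.36 ± 0.01 in TH-S nymphs (12.6-fold), and of p_06496, at -0.25 ± 0.02 and 3.35 ± 0.00 (12.1-fold). The adjusted p-values were 4.92e-16 and 4.4e-17 for the rises and 1.57e-08 and 2.18e-16 for the falls.

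The 2 probes that rose most in TH-R nymphs followed nearly the same course over the 18 arrays, with an SD of 0.0798 for the log2 difference between them. Their sequences do not overlap. The sequence of p_07502 is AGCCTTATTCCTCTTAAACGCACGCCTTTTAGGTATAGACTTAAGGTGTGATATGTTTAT and that of p_00562 is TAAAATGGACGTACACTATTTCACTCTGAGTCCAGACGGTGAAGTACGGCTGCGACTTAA. In adult females p_07502 was at 4.44 ± 0.02 in TH-R and 4.44 ± 0.03 in TH-S, and p_00562 at 3.81 ± 0.03 and 3.91 ± 0.03. The strain effect of p_07502 fell by 3.59 from nymph to adult and that of p_00562 fell by 3.66 (log2, adjusted p = 1.68e-14 and 3.52e-16).

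In nymphs limma called 1739 probes higher and 1474 lower in TH-R, 3213 in all. A change of at least 2-fold was seen for 253 higher and 393 lower probes (86 and 185 with normexp), and among the 4605 probes measured on all 6 nymph arrays for 176 and 229. A group of 42 probes with 40 distinct sequences was well above background in TH-S nymphs and on no TH-R nymph array, up to at least 168-fold lower in TH-R. Only 1 probe had the opposite pattern, at least 5.88-fold higher in TH-R. In the deposited value table the difference of p_00562 was 1.36 and not called (adjusted p = 0.361). That table's value for TH-S nymph replicate 3 equals that of an outlier-marked spot, 13.91, where the other 3 spots of p_00562 read 7.52 to 7.62.

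In unmated adult females the largest rises in TH-R among probes measured on all 6 adult arrays were those of p_06482 and p_06501. Probe p_06482 was at 3.32 ± 0.04 in TH-R and -0.90 ± 0.02 in TH-S, 18.7-fold higher, and p_06501 at 3.09 ± 0.06 and -1.13 ± 0.05, a log2 difference of 4.22 for each. These probes share a run of 35 bases and read the same or closely related transcripts. In nymphs both were lower in TH-R, p_06482 with 2.37 ± 0.01 against 4.15 ± 0.01 and p_06501 with 2.16 ± 0.02 against 3.92 ± 0.04. The largest falls in TH-R adults were those of p_06289, at -1.72 ± 0.02 against 1.08 ± 0.03 (6.94-fold), and p_06620, at -1.65 ± 0.08 against 0.98 ± 0.01 (6.18-fold).

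The adjusted p-values of these adult differences were 1.98e-16 for p_06482, 2.57e-15 for p_06501, 7.89e-11 for p_06289 and 7.97e-09 for p_06620. Limma called 1507 probes higher and 1692 lower in TH-R adults, 3199 in all. A change of at least 2-fold was seen for 310 higher and 190 lower probes (98 and 54 with normexp), and among the 4563 probes measured on all 6 adult arrays for 155 and 125. A group of 85 probes was well above background in TH-R adults and on no TH-S adult array, 20 of them at least 10-fold higher and the highest at least 25.3-fold. Only 9 probes had the opposite pattern, up to at least 6.79-fold lower in TH-R. Of the called probes 47.1% were higher in TH-R with the 75th percentile and 58% with median scaling.

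**Figure D2:**
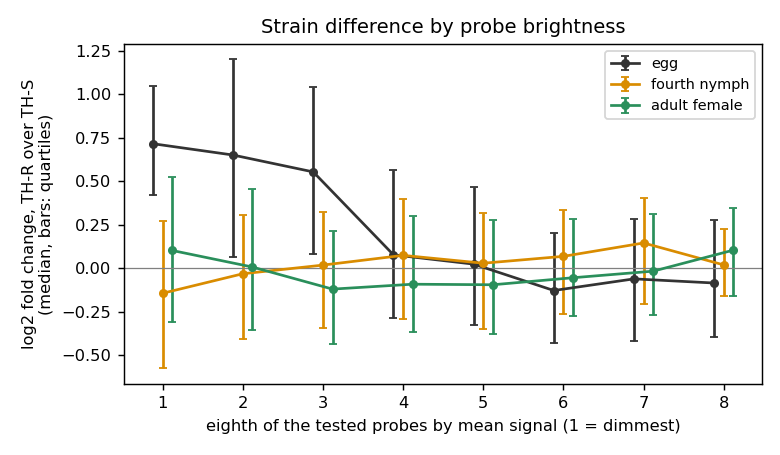
Median log2 fold change of TH-R over TH-S, with quartiles as bars, in each eighth of the 5623 tested probes ordered by mean signal in the stage. In eggs the dimmest eighth had a median of 0.72 and the brightest -0.08, while the medians of the eighths lay between -0.14 and 0.15 in nymphs and between -0.12 and 0.11 in adult females.

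**Figure D3:**
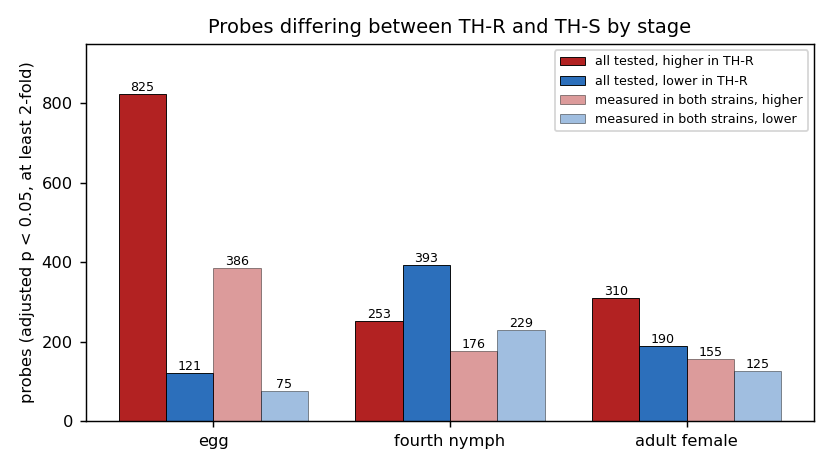
Number of probes with an adjusted p under 0.05 and a change of at least 2-fold between TH-R and TH-S in each stage, for all 5623 tested probes (dark bars) and for those well above background on all 6 arrays of the stage (light bars). The dark bars read 825 higher and 121 lower in eggs, 253 and 393 in nymphs and 310 and 190 in adult females. The egg split changes direction with the scaling, to 291 higher and 1116 lower with median scaling.

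The title of the series asks for stage-specific expression in resistance, so the difference of the strain effect between stages was tested itself. Probe p_06496 was lower in TH-R nymphs (-0.25 ± 0.02 against 3.35 ± 0.00) and higher in TH-R adults (6.26 ± 0.01 against 3.70 ± 0.06). Probe p_06498, which shares 44 bases with p_06482 and 33 with p_06501, was likewise lower in TH-R nymphs (2.26 ± 0.02 against 4.08 ± 0.04) and higher in TH-R adults (3.21 ± 0.02 against -0.95 ± 0.02). Probe p_06434 was at 4.77 ± 0.05 against 6.04 ± 0.01 in nymphs and at 5.40 ± 0.03 against 2.17 ± 0.04 in adults. Probe p_00220 was at -2.11 ± 0.01 against 0.77 ± 0.01 in nymphs and at -0.57 ± 0.03 against -1.61 ± 0.02 in adults. From nymph to adult the strain effect rose by 6.15, 5.98, 4.50 and 3.92 on the log2 scale for these 4 probes (adjusted p of the limma F test, 1.87e-16, 1.87e-16, 2.18e-16 and 2.18e-16).

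Limma's F test of the 2 interaction terms called 4231 of 5623 probes, and for 1696 of them at least 1 pair of stages differed in the strain effect by 2-fold or more (2580 with median scaling, 628 with normexp). With slide as a fixed block, which only sets aside the arrays alone on slides 2 and 3, the count was 4136. At the 2-fold level 84 probes were lower in TH-R nymphs and higher in TH-R adults, where independent lists would share 21.7, and 3 had the opposite course, where 8.55 would be shared. With quantile normalization these counts were 77 and 4, with median scaling 84 and 4, with normexp 38 and 0, and 63 and 2 in the deposited values. At the same level 55 probes were higher and 52 lower in TH-R in both nymphs and adults. Sharing of 2-fold calls by these stages was therefore not particular to opposite courses. Across the 3602 probes measured on all 18 arrays, the strain effects correlated with Pearson's r of 0.261 between egg and nymph, 0.328 between egg and adult and 0.0796 between nymph and adult. These are correlations across probes, which are not independent replicates.

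**Figure D4:**
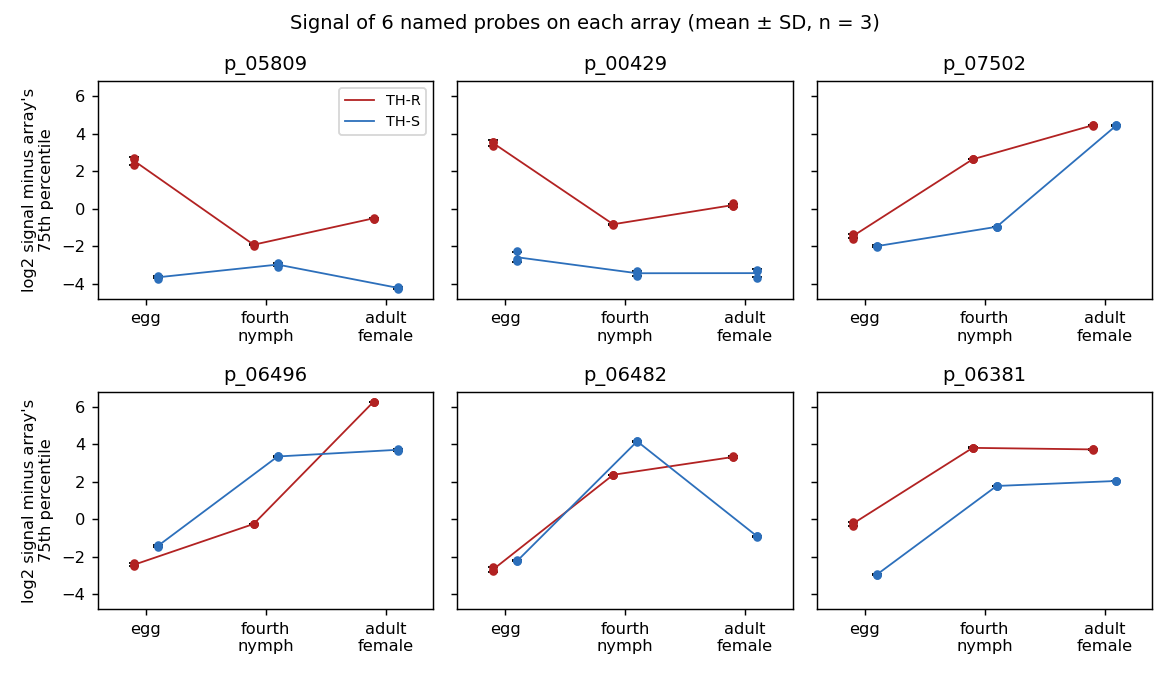
Log2 signal relative to the array's 75th percentile of 6 named probes in each stage, with a point per array and bars for mean ± SD (n = 3). Probes p_06496 and p_06482 were lower in TH-R nymphs and higher in TH-R adults, p_07502 differed in nymphs and was at 4.44 in adults of both strains, and p_00429 and p_06381 were higher in TH-R in all 3 stages.

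Some probes differed in one direction in every stage. Probe p_00429 was higher in TH-R eggs (6.07), nymphs (2.61) and adults (3.63), where its level was 0.19 ± 0.08 against -3.43 ± 0.22. Probe p_06381 was higher by 2.71, 2.03 and 1.68, with 3.81 ± 0.02 against 1.78 ± 0.01 in nymphs. Probe p_02191 was lower in TH-R, with log2 differences of -1.61, -1.42 and -1.28, and p_01765 with -1.08, -0.99 and -1.29. All 12 differences passed in limma, with the largest adjusted p, 2.82e-07, for p_01765 in nymphs.

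Limma called 422 probes higher in TH-R in all 3 stages, where 193 would be shared by independent lists, and 408 lower, where 120.7 would be shared. The balance turned with the scaling, to 314 higher and 445 lower with quantile normalization, 250 and 359 with median scaling, 282 and 392 with normexp and 263 and 396 in the deposited values. With a change of at least 2-fold in each stage, 37 probes were higher and 10 lower, against 21 and 18 with quantile normalization, 22 and 23 with median scaling, 2 and 1 with normexp and 10 and 13 in the deposited values. The 3 strain contrasts share no array, but all 3 set slides 1 and 2 against slides 3 and 4. They also share 1 estimate of spread per probe, so a probe of small spread is more readily called in every stage. Independent lists are therefore no strict baseline for these counts. Calls of opposite direction in nymphs and adults numbered 961, where 918.3 would be shared. In eggs and nymphs they numbered 862 against 1083, and in eggs and adults 806 against 1111.

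Development changed more probes than strain. From egg to nymph, averaged over both strains, p_01994 rose from -2.78 ± 0.06 in TH-R and -4.89 ± 0.11 in TH-S eggs to 3.74 ± 0.05 and 4.23 ± 0.01 in nymphs (226-fold). Probe p_05915 rose from -2.65 ± 0.02 and -3.45 ± 0.08 to 4.92 ± 0.02 and 4.24 ± 0.08 (198-fold). Probe p_00860 dropped from 1.39 ± 0.13 and 2.06 ± 0.02 to -4.12 ± 0.07 and -4.06 ± 0.11 (56.3-fold), and p_07235 from 1.46 ± 0.05 and 2.26 ± 0.06 to -4.07 ± 0.22 and -3.61 ± 0.15 (51.9-fold). Their sequences are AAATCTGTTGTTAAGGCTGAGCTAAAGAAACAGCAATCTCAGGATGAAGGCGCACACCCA for p_01994, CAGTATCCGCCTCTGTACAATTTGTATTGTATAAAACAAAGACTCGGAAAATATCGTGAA for p_05915, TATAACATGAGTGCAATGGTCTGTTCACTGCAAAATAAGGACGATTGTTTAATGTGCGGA for p_00860 and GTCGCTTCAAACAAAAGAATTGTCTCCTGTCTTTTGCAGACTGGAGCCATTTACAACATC for p_07235.

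The log2 differences between nymph and egg were 7.82 ± 0.04 for p_01994, 7.63 ± 0.03 for p_05915, -5.82 ± 0.05 for p_00860 and -5.70 ± 0.07 for p_07235 (standard errors, adjusted p at most 1.31e-18 in limma). Of 5623 probes 2584 were higher and 2551 lower in nymphs, 1874 and 1675 of them by at least 2-fold (1287 and 2987 with median scaling, 888 and 1380 with normexp). Among the 3700 probes measured on all egg and nymph arrays, 1341 were higher and 2075 lower, 750 and 1320 of them by at least 2-fold. At the 2-fold level 1551 probes rose and 1451 dropped in both strains tested apart. The count of calls, 5135, was 5065 with slide as a block, 4750 within slide 1 (TH-R arrays) and 5023 within slide 4 (TH-S arrays). The share of calls that were higher in nymphs was 50.3% with the 75th percentile and 31.1% with median scaling, and the median difference over all probes moved from 0.01 to -1.13 with that scaling and to -0.33 with quantile normalization.

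From nymph to adult female, p_00074 rose from -2.55 ± 0.03 in TH-R and -4.24 ± 0.05 in TH-S nymphs to 1.51 ± 0.03 and 1.92 ± 0.03 in adults (34.5-fold). Probe p_06440 rose from -1.63 ± 0.03 and -0.65 ± 0.02 to 3.63 ± 0.01 and 2.75 ± 0.03 (20.1-fold). Probe p_05903 dropped from 3.07 ± 0.02 and 1.71 ± 0.02 to -4.75 ± 0.21 and -4.20 ± 0.09 (117-fold), and p_06056 from 1.91 ± 0.03 and 2.07 ± 0.03 to -4.26 ± 0.06 and -3.26 ± 0.07 (54.0-fold). Their sequences are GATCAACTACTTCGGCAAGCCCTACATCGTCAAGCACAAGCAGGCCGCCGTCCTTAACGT for p_00074, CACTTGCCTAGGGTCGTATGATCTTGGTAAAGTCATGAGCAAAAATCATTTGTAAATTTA for p_06440, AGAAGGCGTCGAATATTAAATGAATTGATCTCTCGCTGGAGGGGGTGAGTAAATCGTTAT for p_05903 and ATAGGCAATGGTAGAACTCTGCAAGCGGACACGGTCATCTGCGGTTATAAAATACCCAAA for p_06056.

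The log2 differences between adult and nymph were 5.11 ± 0.02 for p_00074, 4.33 ± 0.03 for p_06440, -6.87 ± 0.10 for p_05903 and -5.75 ± 0.04 for p_06056 (standard errors, adjusted p at most 2.14e-16 in limma). Of 5623 probes 2102 were higher and 2476 lower in adults, 522 and 1117 of them by at least 2-fold (953 and 787 with median scaling, 298 and 426 with normexp). Among the 4208 probes measured on all nymph and adult arrays, 1739 were higher and 1769 lower, 327 and 593 of them by at least 2-fold. At the 2-fold level 363 probes rose and 786 dropped in both strains tested apart. The count of calls, 4578, was 4487 with slide as a block, 3649 within slide 1 and 4695 within slide 4. The share of calls that were higher in adults was 45.9% with the 75th percentile and 63.1% with median scaling, and the median difference over all probes moved from -0.06 to 0.29 with that scaling.

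Probes well above background on all 6 arrays of 1 stage and on no array of the other 2 stages numbered 14 for eggs, 42 for nymphs and 15 for adult females. Of the 14 egg probes 1 was higher in TH-R and 13 were not called between the strains. Of the 42 nymph probes 7 were higher and 3 lower in TH-R, and of the 15 adult probes none was higher and 3 were lower.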

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

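The tests of causes for the egg, nymph and adult patterns weighed below were chosen after the results were seen, and the counts of other splits were planned. Limma's F test found 4231 probes whose strain effect differed between stages. Among the probes named in the text, the strain effect (TH-R minus TH-S, log2) changed from egg to nymph by -5.15 for p_05809, -3.46 for p_00429, -3.54 for p_07551, -2.60 for p_01994, 2.13 for p_00822, 3.28 for p_06289 and 0.60 for p_00860. For p_07235 it changed by 0.35, where the single step passed (adjusted p = 0.0377) and the F test did not (adjusted p = 0.0731). From nymph to adult female it changed by 6.15 for p_06496, 6.0 for p_06482, 5.98 for p_06501 and p_06498, 4.50 for p_06434, 3.92 for p_00220, 1.93 for p_05915 and 1.85 for p_06440. Over the same step it changed by -3.21 for p_06620, -3.59 for p_07502, -3.66 for p_00562, -2.11 for p_00074, -1.91 for p_05903 and -0.85 for p_06056. From egg to adult it changed by -1.03 for p_06381 and 0.33 for p_02191. Each was singled out because its strain effect differed between 2 stages in limma.

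The control spot eQC-40, which no comparison uses, read 156 ± 65.5 intensity units in TH-R eggs and 45.7 ± 0.274 in TH-S eggs (mean ± SD, n = 3). Negative control spots read 1.9 and 2.31 in those groups, and eQC-40 read 2.95 to 6.9 in the other groups.

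Other splits of the arrays were counted. In each strain comparison the real split was the only one, 1 of 10, to call as many probes: 3858 against at most 15 in eggs, 3213 against at most 1 in nymphs and 3199 against at most 1 in adults. With 10 splits no share under 0.05 can be reached. Of 100 regroupings, 1, the real one, gave as many calls in the interaction (4231, highest other 3334). It alone did so between nymph and egg (5135, highest other 4348) and between adult and nymph (4578, highest other 3280). This argues against a random grouping of the arrays and no more. Regroupings mix arrays of unlike strains or stages, which widens the spread within groups, and those for the interaction also break the strain effect itself. Whether the arrays of a group stand for separate cultures is unknown, so chance between cultures is not addressed. The real grouping was also the only one for calls in all 3 stages (830, highest other 0). That adds nothing to the splits within a stage, where other splits called at most 15 probes and left almost none to share.

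In eggs, dim probes read higher in TH-R: 557 probes measured on no egg array had a median log2 difference of 0.724 after scaling. Before scaling their median difference was -0.195, while the 75th percentiles of the strains lay 0.919 apart. The rise of these dim probes therefore came with the scaling of arrays of unequal brightness. The dimmest array, TH-R egg replicate 3, is not the whole cause, since 0.362 remained without it. Nor does the shift explain the whole egg difference, since 95 measured probes (69 higher, 26 lower) kept a 2-fold difference in one direction under all 5 scalings. Spike-in controls lay 1.65 ± 0.191 above the 75th percentile in TH-R and 0.578 ± 0.0572 in TH-S eggs (log2, n = 3), which would put the median egg difference of all tested probes at -0.90 relative to them, so unequal RNA or spike-in amounts and a strain difference in the eggs stay open.

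In nymphs, 40 sequences measured in TH-S read 8-fold or more lower in TH-R, readings below background included, and 25 of them were at least 8-fold lower with TH-R held at the lowest measured signal. For 14 of the 40 the TH-S level in eggs or adults left room for such a fall. There the strain difference lay a median 3.39 above that in nymphs (quartiles 1.69 to 4.78), and more than 1 above it for 11 of the 14. This argues against slide or scan day as the whole cause for those 11. The 40 were picked for a large nymph difference, which leans this comparison upward. The rest of the 14, and the 26 that lay near the floor, leave slide or scan day open. Material of one common source in the TH-S samples would keep near-constant ratios between TH-S nymphs and eggs: over the 19 members measured in both, the SD of that difference was 1.98, at percentile 30.6 of random sets (1.28 and 2.23 for 16 members among the 25), which leaves it open for the 40. A part of 12 sequences read 16-fold or more lower (at least 10.2-fold with TH-R so held), was chosen after their values were seen and shared no 15 bases. There the SD over the 10 measured members was 0.427 (5th percentile of random sets, 1.21), so a common source in TH-S nymphs and eggs may account for this part. The median level of the 12 was -4.05 in TH-S eggs, -5.21 in TH-R eggs, -7.21 in TH-R nymphs and -7.2 in TH-S adults. Such a source would then not be confined to TH-S samples, though the scaling may raise dim readings in TH-R eggs. In 6 of the 40 some TH-R stage reached 0.5 of the TH-S nymph level or more (2 within 2-fold, 4 above that), and each stage was sampled at a single moment, so a difference in developmental moment and a strain difference stay open.

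In adult females, 62 sequences measured in TH-R read 8-fold or more higher there, and 53 were at least 8-fold higher with TH-S held at the lowest measured signal. Slide or scan day is argued against by the nymphs on the same slides, where the median difference was -1.68 (quartiles -2.05 to -0.75). Nymph material carried into the TH-R adult samples is argued against by levels above those of TH-R nymphs, with a median difference of 0.989 (quartiles 0.595 to 1.53, 57 of 62 above 0). Adults sampled at different distances from the nymph stage could be a cause, as 43.6% of the 273 probes measured in adults of a strain and 2-fold higher in TH-R were 2-fold higher in nymphs than adults, against 13.5% of the 4532 without a 2-fold strain difference, but this share uses arrays that define the pattern. By TH-R arrays alone, where that bias runs against such a cause, it was 15.4% against 13.2%, and by TH-S arrays alone 63% against 15%, where it runs in favour, so timing and a strain difference both stay open.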

How the results depend on the processing

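The tests with a weight per group, with probes measured on all 6 arrays of a stage and within slide 1 or 4 were chosen after the results were seen. The balance of egg calls moved with the scaling, from 60.3% higher in TH-R to 19% with median scaling. Apart from the counts named next, each count of calls stayed within 1.5 times its value under every alternative run, though the probes could differ. With at least 2-fold required, 946 probes were called in eggs, 646 in nymphs, 500 in adults, 1696 in the interaction, 47 in all 3 stages and 1639 between adult and nymph, since the threshold is stricter. With probes measured on all 18 arrays alone, 3359 were called between nymph and egg, since only 3602 were tested. Calls in eggs ranged from 2796 (probes measured on all 18 arrays) to 4054 (no filter), in nymphs from 2435 (all 18) to 3927 (array weights) and in adults from 2424 (all 18) to 3868 (array weights), the 2-fold threshold aside. A weight per group gave 3187 calls in eggs. Of the 3858 egg calls, 2289 were called in the same direction with median scaling, 2818 with quantile normalization and 2775 with normexp. In the deposited values, 2679 of the 3857 egg calls present there kept direction and call. The lowest such numbers with these scalings were 2708 of 3213 in nymphs (normexp) and 2605 of 3199 in adults (deposited values). Egg counts of similar size therefore held partly different probes.

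Leaving out each array in turn gave 3554 to 3865 calls in eggs, 2971 to 3576 in nymphs, 2950 to 3662 in adults, 4066 to 4400 in the interaction, 778 to 945 in all 3 stages, 5047 to 5185 between nymph and egg and 4465 to 4779 between adult and nymph. Where a group then had 2 arrays, their spread was taken from all groups.

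The replicate numbers do not pair the arrays: same-number pairs had a median correlation of deviations of -0.00187 (-0.242 to 0.203, 2 of 45 over 0.1), and 4 of 18 arrays correlated best with their own number. With the replicate number as a block 3832, 3181 and 3169 probes were called in eggs, nymphs and adults, 4225 in the interaction, 816 in all 3 stages, 5125 between nymph and egg and 4554 between adult and nymph, so the block moved no count past 1.5 times. With slide as a random block (consensus correlation -0.0627) the strain counts were 3971, 3352 and 3348, with 874 shared. Strain and slide are confounded, so this block cannot remove a slide effect from these counts.

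For the single probes named, 377 of 378 values recomputed under the alternatives set beforehand, all 630 with an array left out and all 74 under added ones kept direction and call. The exception was p_00562 in nymphs, 1.36 in the deposited table. Some alternatives, such as the replicate block, leave the log2 difference of a probe as it is. The named probes were picked from these same data for large changes or small p-values, so they could hardly lose direction or call. Their sizes moved more: of 35 values, 16 moved by over 1.5-fold with normexp, all toward 0 (p_01994 between nymph and egg from 7.82 to 5.93), 11 with median scaling, 5 with quantile normalization and 7 in the deposited table, and 4 of 8 within slide 1 and within slide 4. Gene list tests could not run, as no probe has a description, and the setting with the compared stages alone does not apply to the interaction. Signal over background limits the dim probes: 557 tested probes were measured on no egg array, and their strain differences follow the scaling.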

Other observations

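The tests of an excess called higher were set before their results were seen, while those of an excess called lower had no prediction and the count of opposite courses was chosen after. The array's probes have no gene names here, so the 7211 distinct sequences were translated in 3 forward frames and searched for textbook protein signatures. A signature of cytochrome P450s, enzymes that can break down insecticides, was found in 33 sequences, against 1 on the reverse strand. A signature of HSP70 chaperones, proteins that fold other proteins and rise under stress, was found in 9 sequences and in none on the reverse strand. A signature names no gene, and single members are not named.

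Of the 28 P450-signature sequences tested (23 that do not overlap), 11 were higher and 13 lower in TH-R eggs, 10 higher and 8 lower in nymphs and 9 higher and 9 lower in adults. The hypothesis was that members were higher in TH-R more often than other sequences, as the metabolism of an insecticide could require. The shares called higher were 39.3% in eggs, 35.7% in nymphs and 32.1% in adults, against 40.8%, 30.9% and 26.5% of other sequences (Fisher's exact p = 1, 0.547 and 0.521, two-sided). No excess called higher passed the test, and with 28 sequences a small one would be missed. In eggs 46.4% were called lower against 27.4% of others, opposite to the hypothesis (Fisher's exact p = 0.0327, adjusted over 12 tests 0.196, and 0.0967 to 0.555 with the other scalings). In eggs the balance moved with the scaling, from 11 higher and 13 lower to 7 and 19 with median scaling. It also turned with the threshold: 7 were higher and 3 lower by at least 2-fold, where all tested probes gave 825 and 121.

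Of the 9 HSP70-signature sequences, 7 were lower and none was higher in TH-R nymphs, with a median log2 difference of -1.46. The hypothesis of an excess called higher gave 44.4% in eggs, 0% in nymphs and 44.4% in adults, against 40.8%, 31% and 26.5% of other sequences. In nymphs the share called lower, 77.8% against 27%, was larger (Fisher's exact p = 0.00222, adjusted over 12 tests 0.0266), opposite to the hypothesis. The test takes the 9 sequences as independent, but 4 of the 7 were also at least 2-fold higher in TH-R adults and may move together. Another of the 7, at -6.11, is among the 12 sequences above for which a common source stays open. With each other scaling, and in the deposited values, 6 were lower and 0 higher, and the adjusted p was 0.06 to 0.117, so the excess passes with the 75th percentile alone, while the median difference was -1.24 to -1.64 with the others. With none of the 9 called higher under any of these scalings, the values argue against an excess called higher in nymphs. In adults 4 were higher, with log2 differences of 2.51 to 4.36, and 3 lower, with -0.19 to -0.32. Under every scaling 4 or 5 were higher. In eggs 4 were higher and 1 lower, which turned to 1 and 6 with median scaling.

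At the 2-fold level 80 sequences were lower in TH-R nymphs and higher in TH-R adults, 4 of the 9 HSP70-signature sequences among them. This count was taken after the values above were seen and tests no explanation.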
